A study of Homo sapiens with 7 samples.

How the data were processed

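Per the labels, total RNA of BHT-101 cells, a human anaplastic thyroid cancer line, was isolated on columns with DNase digestion and made into Illumina TruSeq RNA libraries. How ribosomal RNA was avoided is not given in the sources used here. The 7 libraries are 3 biological replicates of wild-type (WT) cells and 4 knockout (KO) clones of ASH1L with 1 library each. Clones are named KO1 to KO4 as the labels name them.

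The values deposited by the authors are log2 RPKM, that is log2 reads per kilobase of gene and 1e6 reads, for 13142 genes in 1 table. Per the submitters' processing notes, Trim Galore 0.4.1, STAR 2.5.3a, HTSeq 0.11.2 and edgeR were used with build hg38. No version of the last tool, no gene annotation, no prior count and no filter are given in the sources used here. The table gives no read totals. Genes without reads share a low value that depends on gene length. A prior count of 0.25 reads was assumed and no other was tried. The steps between the lowest values then gave relative library sizes with a mean of 1.002. From these steps the effective library sizes were estimated at 56.5, 63.2 and 59.7 M reads for WT1, WT2 and WT3, and at 49.2, 63.8, 44.0 and 70.3 M for KO1, KO2, KO3 and KO4. Between 20.8% and 27.9% of the low values came out whole within a tolerance of 0.03 reads at the best scale, so the sizes are estimates and reads were not recovered; no count test was run. At the median exon length of 3.72 kb and the mean library of 58.0 M reads, 1 RPKM stands for about 215 reads, which gives a counting error of 6.8%. A log2 fold change of a gene near the level without reads depends on the prior count and is not a measure of size, so levels are given for such genes. Strand was not stated for the counting, so reads of overlapping genes cannot be told apart.

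Genes were kept when log2 RPKM was above 0 in at least 3 of the 7 libraries, which left 11154 genes. No further scaling and no pseudocount was applied. KO and WT were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a trend on the mean level, Benjamini-Hochberg adjustment, adjusted p under 0.05), with the 4 clones as replicates of the knockout. Each clone was also set against WT, with the spread taken from the 3 WT samples, on the assumption that a lone clone varies like them. The clones with a stop codon before residue 1500 (early-stop, KO1 and KO2) were compared with the others (late-stop, KO3 and KO4) in a fit of all 7 libraries. ASH1L was also tested by an exact two-sided permutation test over the 35 splits. Adjusted p-values below are from limma unless another test is named. In total 32 gene lists were fixed, of which the 29 with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated one.

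Groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule named ASH1L; for KO against WT up to 12 genes per direction with the largest log2 fold change among those with adjusted p under 0.05, all 4 clones on one side of all 3 WT samples and a mean log2 RPKM of at least 1 in the higher group; up to 5 per direction for late-stop against early-stop clones, filled to 3 by unadjusted p; 3 per direction for each clone; up to 10 genes called in all 4 clones; and up to 4 members of each list by smallest unadjusted p. Symbols of unnamed transcripts were counted and not named. Gene positions were taken from GENCODE release 29, on the build the notes name; 12512 of the 13142 genes (95.2%) were matched, 208 of them through synonyms.

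Chromosome positions were examined after the calls had been seen. The median log2 difference from the WT mean, with each library's median over all genes set to 0, was taken in 212 bins of 10 Mb with at least 20 tested genes. For a position-centred setting, the median difference of the genes within 5 Mb was subtracted from each gene. A list of 70 endodermal and hepatic genes was written after the lowest genes of KO1 had been seen.

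The procedures were tested on simulated log2 values with the means and spreads of the 11154 tested genes and 200 changed genes. For KO against WT, 46.0% of genes changed by 1 log2 unit and 84.0% of those changed by 2 were called, with 9 false calls. For a single clone against WT the shares were 57.0% and 83.0%, with 3 false calls, when clones were simulated with the spread of the WT samples. For late-stop against early-stop clones they were 44.0% and 75.0%, with 123 false calls. The WT samples, which vary less, enter that fit, but whether they cause the false calls was not tested. A list of 42 genes raised in the simulated clones was called and no other list was. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called without a change. A simulated loss of 0.60 log2 units over the 584 genes of 1 chromosome had a median of -0.60 before position centring and 0 after it.

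The alternatives covered the filter, a pseudocount of 1, scaling, the variance model, weights per group, the replicate number as a block, an estimated correlation, a minimum fold change and leaving out each library. The replicate numbers did not pair WT samples with clones. Figures were drawn with matplotlib 3.10.9. Results of some single genes are not reported here.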

Results

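RNA-seq was used to compare wild-type BHT-101 cells with clones carrying premature stop codons in ASH1L, a histone methyltransferase of the Trithorax group. The labels place the stop after residue 413 in KO1, 610 in KO2 and 2129 in KO3, each on both alleles, and after residues 2169 and 2174 in KO4. The 3 WT samples were close to each other, with Pearson correlations across the 11154 tested genes of 0.988 to 0.995. KO1 stood farthest from WT, at 0.821 to 0.830, while KO2, KO3 and KO4 lay between 0.913 and 0.940. The median SD over genes was 0.10 log2 units among the WT samples and 0.30 among the clones, and the clones had the larger SD in 90.4% of genes. No clone with intact ASH1L was analysed. The changes below therefore cannot be divided between ASH1L loss and other differences of the clones from WT. Estimated library sizes ran from 44.0 to 70.3 M reads.

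The targeted gene was examined first. ASH1L (ENSG00000116539, chromosome 1, 155335268 to 155562807, minus strand, hg38) was at log2 RPKM 3.34, 3.30 and 3.22 in WT1, WT2 and WT3. It was lower in KO1, KO2 and KO3, at 2.69, 2.54 and 2.42, which is 0.66, 0.60 and 0.55 times the WT mean. In KO4 it was higher, at 3.74, or 1.37 times the WT mean. The single-clone fits gave adjusted p = 0.00556, 0.00430, 0.00234 and 0.0272 with limma, but they take the spread from the WT samples, and the clones varied more than these. As a group, the clones averaged 2.85 ± 0.61 (SD, n = 4) against 3.29 ± 0.06 (SD, n = 3), a difference of -0.44 ± 0.31 (SE) that did not pass (adjusted p = 0.512; exact two-sided permutation p = 0.257 over 35 splits, the smallest possible being 0.0286). A premature stop codon need not lower a transcript, so these levels do not test the labels.

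**Figure D1:**
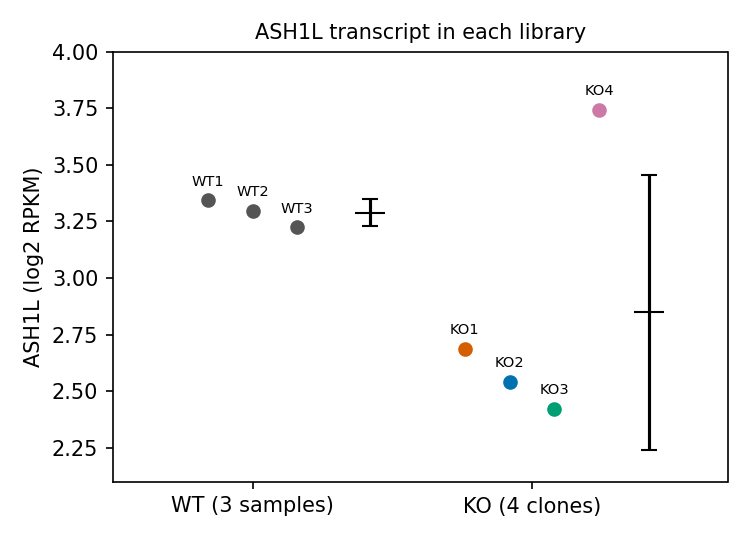
ASH1L transcript level (log2 RPKM, vertical axis) in each WT sample and each KO clone, with the mean and SD of each group as bars. KO1, KO2 and KO3 lie between 2.42 and 2.69, below the WT samples, and KO4 lies above them at 3.74.

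Among the transcripts that passed for KO against WT and met the level rule, those of IGFBP7, RNF212 and SLC1A1 rose most. IGFBP7, a secreted binding protein of insulin-like growth factors, rose from a mean log2 RPKM of -2.77 ± 0.34 (SD, n = 3) to 1.56 ± 0.93 (SD, n = 4). FBN1, which encodes the microfibril protein fibrillin, rose 3.48-fold (log2 fold change 1.80 ± 0.25 SE, adjusted p = 0.0420). BMP4, a secreted growth factor, rose 3.73-fold (1.90 ± 0.27, adjusted p = 0.0424), and GLI3, a transcription factor of the Hedgehog pathway, rose 5.66-fold (2.5 ± 0.35, adjusted p = 0.0420). Among transporters, SLC1A1, a glutamate carrier, rose 8.48-fold (3.08 ± 0.23, adjusted p = 0.00970), and SLC46A1, the proton-coupled folate carrier, rose 3.68-fold. The smallest adjusted p was shared by SLC1A1 and RNF212, a RING-type protein of meiotic recombination, which rose 9.94-fold (3.31 ± 0.24). NUDT11, ATP10D, NUP210, RNF208 and FNDC10 rose by log2 fold changes of 2.13, 1.69, 1.56, 1.41 and 1.34.

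Among transcripts that fell, VSTM2L dropped by 2.55 on the log2 scale, MORC4 by 2.21 and SCARA3, a scavenger receptor family member, by 1.64. TSSC2 was at a mean log2 RPKM of 1.98 in WT and between -5.42 and -3.14 in the clones, which is near the level without reads. H1F0, a linker histone, dropped by 1.01. The others that the rule named all lie on the distal long arm of chromosome 11: UBASH3B, a phosphatase that acts on tyrosine kinases, dropped by 1.46, NRGN by 1.21, ACAT1, a mitochondrial acetyl-CoA acetyltransferase, by 1.12, TAF1D by 1.10, DCUN1D5 by 1.07, the ribosomal protein gene RPS25 by 0.98, and RDX, which encodes the actin linker radixin, by 0.98. In each of these named genes all 4 clones lay on one side of all 3 WT samples, as the naming rule required.

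In total 46 genes passed, 19 higher and 27 lower, against 1753 with an unadjusted p under 0.05. With quantile normalization 114 genes passed and the share of higher calls was 56.1%, against 41.3% as reported. The count rests on single libraries: 0 genes passed without any 1 of the WT samples, 1 without KO4, 88 without KO3 and 248 without KO2. All 4 clones lay on one side of all WT samples in 2119 genes (19%).

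**Figure D2:**
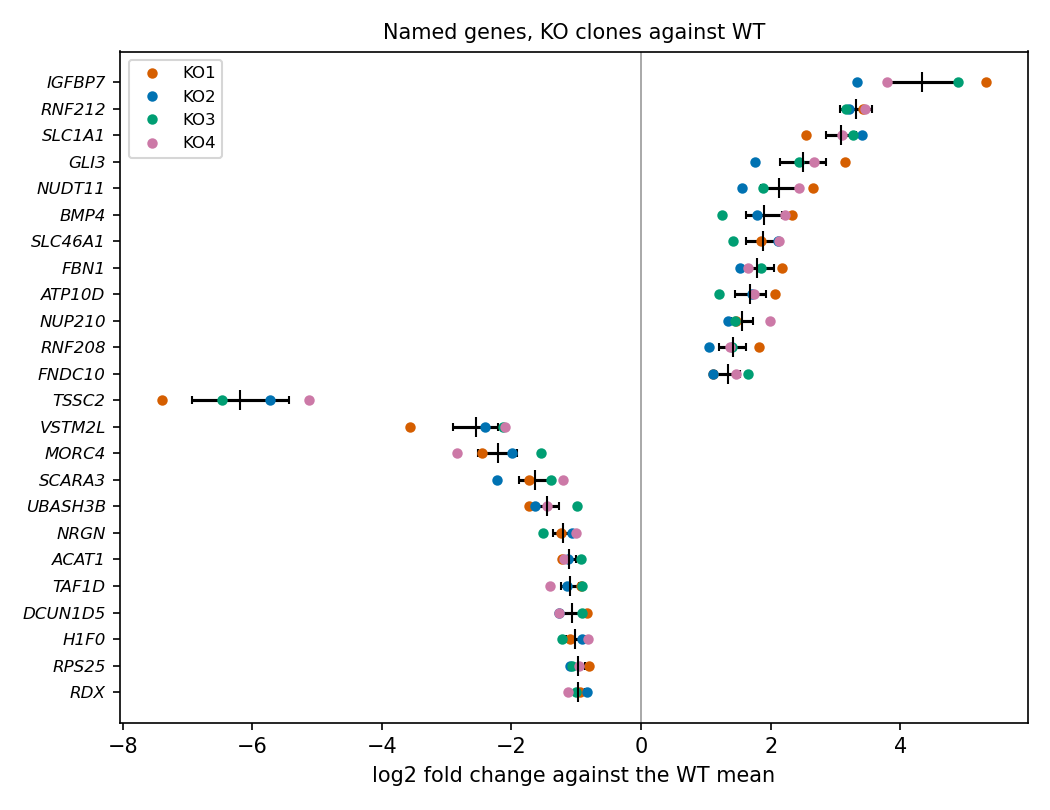
Log2 fold change against the WT mean (horizontal axis) of the 24 genes named for KO against WT, with 1 point per clone and the limma estimate with its SE as a black bar. All 4 clones lie on the same side of 0 for each gene, as the naming rule required.

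The falling genes were not spread evenly over the genome. Of the 26 lower genes with a known position, 17 lay on chromosome 11 between 90201160 and 134265855 (hg38), a stretch with 149 of the 10722 positioned genes (Fisher's exact test, one-sided, p = 2.96e-26; the stretch was chosen after the calls were seen). Over the 23 chromosomes tested, chromosome 11 was enriched for lower genes (adjusted p = 1.59e-15) and chromosome 4 held 4 of 18 higher genes (adjusted p = 0.0902). The median log2 difference over the 149 genes was -0.64 in KO1, -0.63 in KO2, -0.64 in KO3 and -0.72 in KO4, and between -0.03 and 0.02 in the WT samples. In 77.9% of these genes all 4 clones were below the WT mean, against 14.6% elsewhere. When each gene was set against its neighbours within 5 Mb, an alternative chosen after seeing the data, RNF212 alone passed, with a log2 fold change of 3.25 ± 0.22 (SE, adjusted p = 0.0140). All 24 named genes kept their direction there. Outside the stretch, fold changes moved less than inside it: SLC46A1 went from 1.88 ± 0.26 to 1.54 ± 0.29 with adjusted p = 0.136, IGFBP7 from 4.34 ± 0.54 to 4.16 ± 0.49 with adjusted p = 0.0693, and FBN1 from 1.80 ± 0.25 to 1.7 ± 0.25 with adjusted p = 0.0926. Inside it, RPS25 went from -0.98 ± 0.11 to -0.36 ± 0.11 and RDX from -0.98 ± 0.12 to -0.29 ± 0.10. Leaving the stretch out altogether left 2 genes past the threshold, RNF212 and SLC1A1. Dropping genes cannot change the fold changes of the others, for example 4.34 for IGFBP7, so these are not tested by it. Only the moderated variances and the adjustment over genes can change in that setting.

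Other chromosome stretches shifted in some clones. Of 212 bins of 10 Mb, 60 in KO1, 30 in KO2, 40 in KO3 and 25 in KO4 had a median beyond 0.3 log2 units, while no WT bin did and the WT bins lay between -0.11 and 0.07. On chromosome 1 from 140 Mb, which holds ASH1L, the median of 474 genes was -0.63 in KO1 and 0.13, 0.12 and -0.10 in KO2, KO3 and KO4. On chromosome 7 from 90 Mb the median of 283 genes was -0.70 in KO1 and between -0.28 and -0.18 in the others. On the X chromosome below 80 Mb it was -0.67 in KO1 and -0.73 in KO3, against 0.14 in KO2 and 0.07 in KO4. Chromosome 9 was higher in KO1, KO2 and KO4, with medians of 0.48, 0.38 and 0.29, and at 0.04 in KO3. Some bins moved together in all 4 clones. The bin of chromosome 17 from 20 to 30 Mb, which holds SLC46A1, was at 0.455, 0.294, 0.454 and 0.237 in KO1 to KO4. The bin of the X chromosome from 100 to 110 Mb, which holds MORC4, was at -0.347, -0.234, -0.364 and -0.376. Against its 128 neighbours within 5 Mb, ASH1L was at -0.24 in KO1, -0.56 in KO2, -1.01 in KO3 and 0.30 in KO4.

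**Figure D3:**
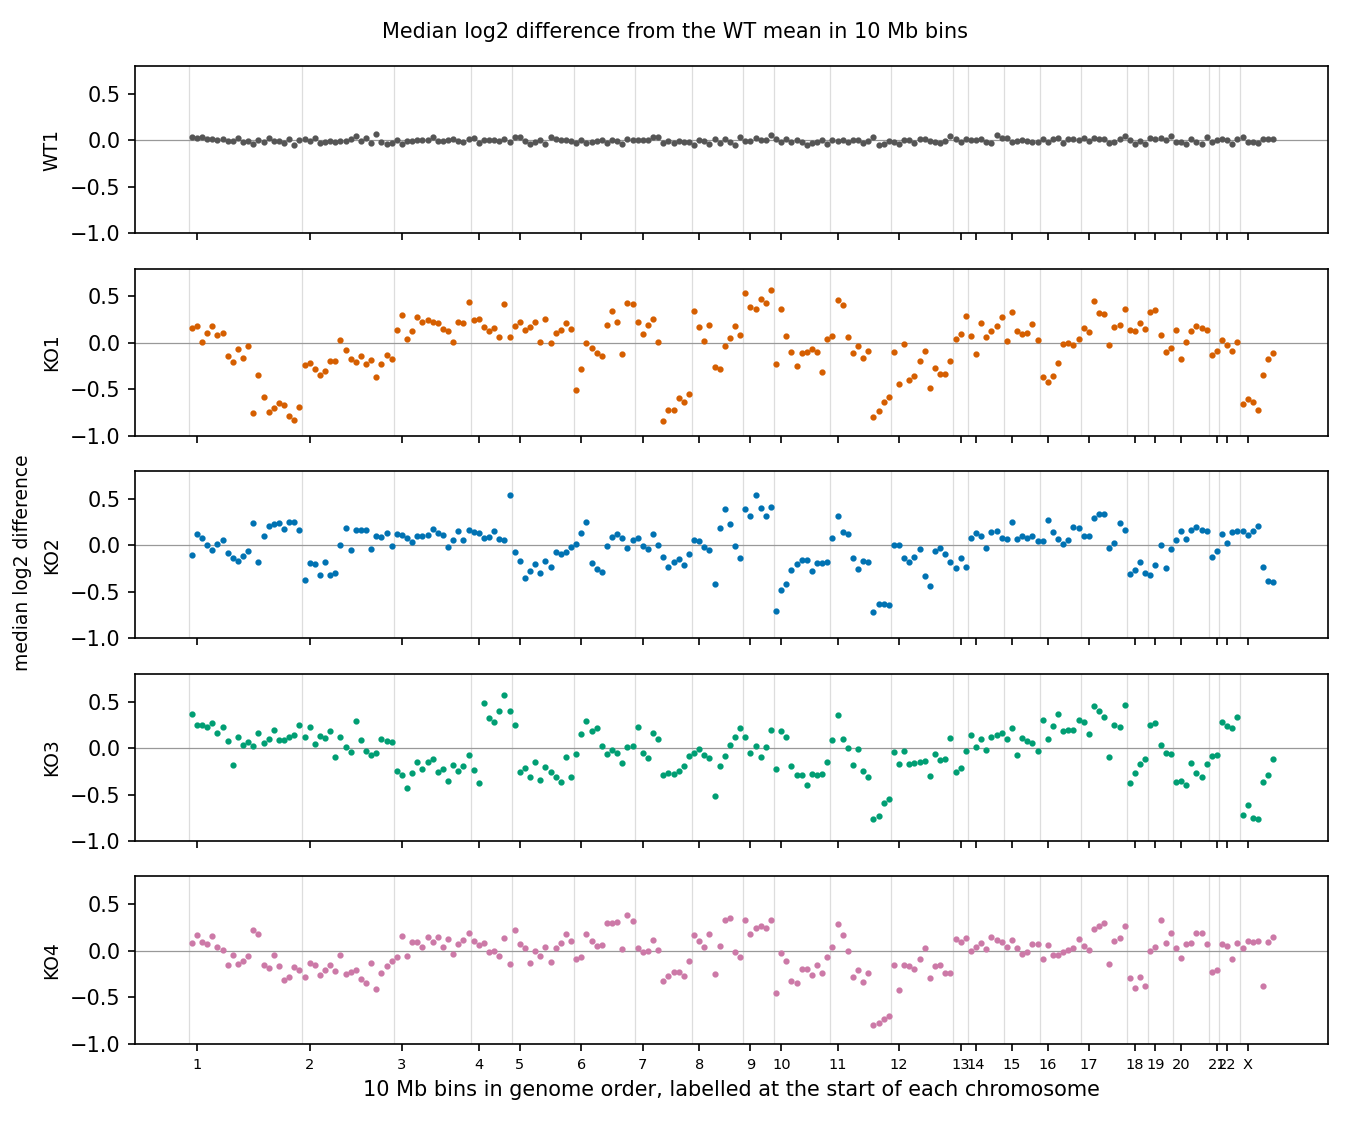
Median log2 difference from the WT mean (vertical axis) in 212 bins of 10 Mb in genome order (horizontal axis), for WT1 and the 4 clones. WT1 stays near 0, the end of chromosome 11 is low in all 4 clones, and the long arms of chromosomes 1 and 7 are lowest in KO1.

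Of the lists fixed beforehand, 5 passed at the preset correlation and none with an estimated one (camera, adjusted p = 0.910 for each of the 5). Genes of the G2 and M phases of the cell cycle were higher at the preset correlation: 42 of 52 had a positive log2 fold change, with a median of 0.18 (camera, adjusted p = 0.000751) and clone medians of 0.41, 0.02, 0.12 and 0.20 in KO1 to KO4. TOP2A and BIRC5 were at log2 fold changes of 0.47 ± 0.11 (SE) and 0.43 ± 0.12, and no member passed on its own. These genes lie on chromosome 17, in bins whose median was above WT in every clone. The bin from 40 to 50 Mb, which holds TOP2A, was at 0.312, 0.336, 0.334 and 0.293 in KO1 to KO4. The bin from 70 to 80 Mb, which holds BIRC5, was at 0.189, 0.241, 0.229 and 0.135. The rises of TOP2A and BIRC5 were not separated from these shifts. BIRC5 was at 5.47, 5.34 and 5.20 in WT1, WT2 and WT3, so that WT1 lay closest to the clones. Of 23 replication-dependent histone genes fixed, 8 had values and 7 were tested. All 7 were higher (median 0.62, camera, adjusted p = 0.00857), with clone medians of 1.03, 0.71, 0.57 and -0.02 in KO1 to KO4. HIST1H2AC, HIST1H2BD and HIST1H2BK lie in the bin of chromosome 6 from 20 to 30 Mb, so the members need not be independent. That bin was at 0.003, 0.253, 0.288 and 0.181 in KO1 to KO4. Targets of ATF4 and the unfolded protein response were lower: 24 of 29 were negative, with a median of -0.52 (adjusted p = 0.00624), among them TRIB3 at -1.59 ± 0.34 and ATF4 itself at -0.51 ± 0.15, neither of which passed on its own. The WT samples differed in these genes, with TRIB3 at 5.86, 6.54 and 7.24 and ATF4 at 7.36, 7.64 and 7.92 in WT1, WT2 and WT3, so that WT1 lay closest to the clones. Targets of NRF2, the regulator of the oxidative stress response, were negative in 16 of 20 (median -0.46, adjusted p = 0.0237), although the clone median was 0.31 in KO2; HMOX1 was at -1.35 ± 0.28 and did not pass (adjusted p = 0.0964), with 3.12, 3.46 and 4.26 in WT1, WT2 and WT3. Nuclear genes of oxidative phosphorylation were negative in 25 of 37 (median -0.12, camera, adjusted p = 0.0475). SDHD, on distal chromosome 11, was the only member that passed over all genes (-0.96 ± 0.14, limma, adjusted p = 0.0493), and 2 were lower when adjusted over the list alone. Without WT3 1 list passed, without WT2 9 and without KO4 3.

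The remaining 24 tested lists did not pass (adjusted p = 0.0599 to 0.952). Those nearest to ASH1L's known roles were close to 0: the median was 0.02 over 21 genes of histone H3 lysine methylation and ASH1L partners, 0.04 over 26 Polycomb genes, and 0.01 over 13 HOX genes and cofactors. HOXB8 was at -1.95 ± 0.38 (adjusted p = 0.0850) and CBX6 at 0.62 ± 0.11 (adjusted p = 0.0682). Adjusted over the list alone, 1 gene of the first list passed, which was lower, 4 Polycomb genes passed, 3 higher and 1 lower, and 1 HOX gene passed, which was lower, against 0 over all genes. Genes of the extracellular matrix had a median of -0.22 while camera pointed up (adjusted p = 0.838), with 1 member higher over all genes, FBN1, and 5 higher and 1 lower when adjusted over the list alone. Among p53 targets ZMAT3 rose (1.17 ± 0.16, adjusted p = 0.0420). Outputs of MAPK signalling had a median of -0.12 (adjusted p = 0.838), and the 5 tested thyroid differentiation genes one of 0.47 (adjusted p = 0.440). Epithelial junction and keratin genes had a median of -0.59 (adjusted p = 0.0599), from -1.30 in KO1 to 0.23 in KO2.

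**Figure D4:**
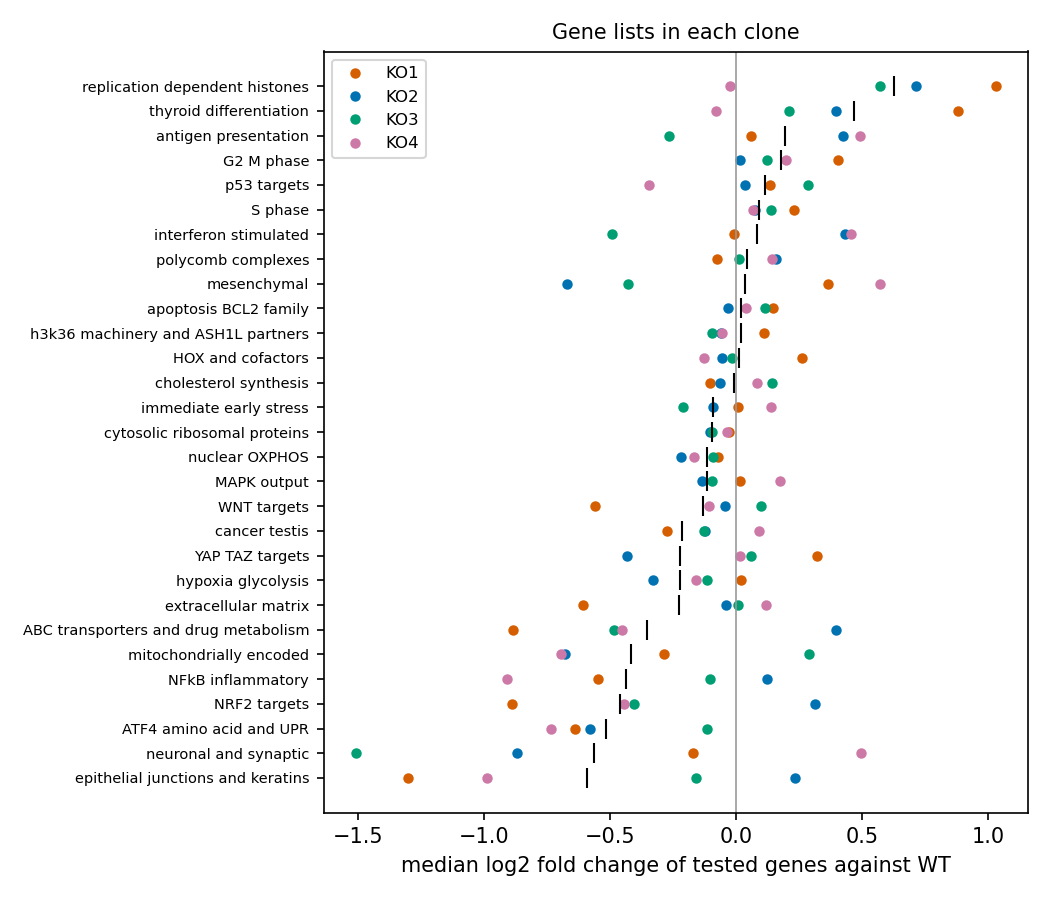
Median log2 fold change against WT (horizontal axis) of the tested genes of each of the 29 lists, with 1 point per clone and the KO against WT median as a black bar. Replication-dependent histones are at the top with 0.62 and epithelial junctions and keratins at the bottom with -0.59.

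Few markers of cells that a carcinoma line should not hold could be tested. Of 15 leukocyte markers 4 were in the table and 1 was tested, CD3D, on distal chromosome 11, at a mean log2 RPKM of 3.24 in WT and from -7.75 to -0.47 in the clones (adjusted p = 0.153). Of 15 fibroblast and endothelial markers 4 were in the table, 3 were tested and none passed; LUM was at 5.31 in WT and 4.94 in KO, COL1A1 at 2.12 and 1.03, and PDGFRA at 3.21 in WT and from -6.82 to 2.37 in the clones.

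Each clone was also set against WT singly, with the WT spread standing in for that of the clone. In KO1, SPOCK1, a matrix proteoglycan gene, rose from a WT mean of -2.82 to 4.27, PRICKLE1, a planar cell polarity gene, from -4.28 to 2.48, and SLITRK4 from -5.83 to 1.56. The same rule named these 3 genes in KO3, at 3.98, 1.48 and 2.09, while KO4 had SPOCK1 at 3.52, PRICKLE1 at 1.37 and the heparan sulfatase gene SULF2 at 4.87 against -4.13 in WT. HABP2, the keratin gene KRT4 and HHLA2 were at 4.60, 2.65 and 2.33 in WT and at or near the level without reads in KO1, at -9.73, -9.59 and -9.72. In KO2, SULF2, the imprinted RNA H19 and LY6D rose to 3.44, 5.89 and 4.23, from -4.13, 1.02 and -0.44, and HAPLN1, TSSC2 and the long noncoding RNA CCAT1 fell to -4.30, -3.75 and -3.24. In KO3 the cell cycle inhibitor gene CDKN2B, the defensin gene DEFB1 and SERPINB4 fell from 3.26, 3.90 and 1.84 to -9.88, -6.79 and -6.22. In KO4 CCAT1, the fibrinogen gene FGA and KRT4 fell from 2.34, 1.35 and 2.65 to -8.95, -9.84 and -7.48.

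The counts of genes past the threshold were 4919 in KO1 (2138 higher, 2781 lower), 3736 in KO2 (1724, 2012), 3805 in KO3 (1588, 2217) and 2769 in KO4 (1159, 1610). These tests compare single libraries with WT and include whatever differs between clones; the clones had the larger SD in 90.4% of genes, so the p-values take too small a spread. Without WT2 the counts were 3014, 1664, 1620 and 1099, and with quantile normalization the share of higher calls in KO1 was 53.7% against 43.5%.

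**Figure D5:**
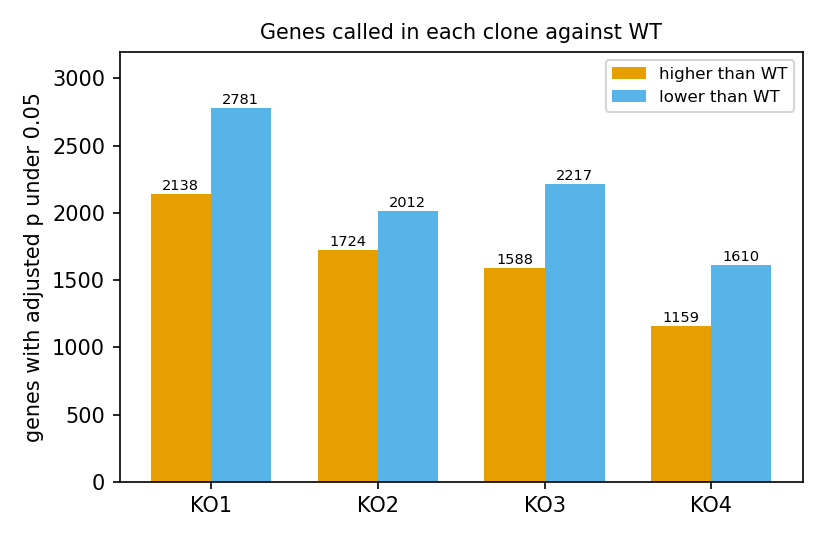
Number of genes with adjusted p under 0.05 (vertical axis) in each clone against WT, split by direction. KO1 has the most, with 2138 higher and 2781 lower.

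In all 4 clones 126 genes were higher and 257 lower. Among those with a mean log2 RPKM of at least 1 in the higher group, large mean rises were seen in SPOCK1, IGFBP7, RNF212 and SLC1A1. Large mean drops were seen in CCAT1, HABP2, KRT4, DEFB1 and TSSC2. For HABP2, KRT4 and DEFB1 the mean rests on clones at or near the level without reads. HABP2 was at 3.55 in KO2 and -9.73 in KO1, against 4.60 in WT. KRT4 was at 1.31 in KO3 and -9.59 in KO1, against 2.65. DEFB1 was at 2.585 in KO2 and -6.79 in KO1, against 3.90. Independent lists with as many genes as the calls of each clone would share 4.9 and 14.4 genes, without allowing for the shared WT samples. Of the 257 lower genes, 66 lie in the distal stretch of chromosome 11. Log2 fold changes correlated across genes with a mean Pearson r of 0.367 between clones. Simulated unchanged clones gave 0.25 because of the shared WT samples, but they were drawn with the spread of the WT samples. The real clones had the larger SD in 90.4% of genes, so 0.25 is no comparison value for these correlations. The mean covariance was 0.279 against 0.0063 in the simulation. KO1 and KO4 were closest (r = 0.754), followed by KO1 and KO3 (0.546), and KO1 and KO2 were farthest apart (0.059), with 832 genes called in opposite directions. The simulated covariance covers the scatter among the WT samples, but not a difference that all 3 of them share. Part of the excess may come from such a difference, and genes are not independent replicates.

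The position of the stop codon separates KO3 and KO4 (late) from KO1 and KO2 (early). In this comparison 0 genes passed with limma, 436 had an unadjusted p under 0.05 and the lowest adjusted p was 0.252. The genes with the smallest p, none of which passed, were TRIB2, MLLT11 and COL6A3 toward higher values in late-stop clones, with log2 differences of 2.12 ± 0.20 (SE), 2.61 ± 0.30 and 3.91 ± 0.51, and MTUS1, ALCAM and CDCA7L toward lower values, at -1.67 ± 0.25, -0.84 ± 0.15 and -1.68 ± 0.31. Cholesterol synthesis genes were higher in late-stop clones as a list (median 0.20, camera, adjusted p = 0.00138), and replication-dependent histone genes lower (median -0.56, adjusted p = 0.000376); with an estimated correlation the adjusted p was 0.354 and 0.489. Without KO1 or without KO2 genes passed, when the remaining early-stop clone was assumed to vary like the other libraries. Their directions were opposite: most were lower in late-stop clones without KO1 and most were higher without KO2. Each class holds 2 clones, so differences between clones are part of this comparison.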

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

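These checks of single clones followed rules set before the data were examined. Of 168 named genes, 10 had 1 clone set apart from the other 3 by more than 0.83 of the range, and none of the 29 list medians did. A rate of 1 in 20 would give about 8.4 genes. Some of these genes were named for their change in 1 clone, so that rate is no fair comparison.

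SLITRK4 (gap 0.876 of the range) and SPOCK1 (0.846) stood apart in KO2, at log2 RPKM -7.95 and -0.58, while the other clones were at 0.85 to 2.09 and 3.52 to 4.27. In KO3, CDKN2B (0.842) was at -9.88 against 0.77 to 2.76 in the other clones, DUSP5 (0.874) at 4.91 against 5.39 to 5.46, and HERC6 (0.835) at 0.26 against 0.97 to 1.11. RPS27A (0.886) was at 8.15 in KO3 against 7.89 to 7.92, and HIST2H2BE (0.909) at 1.19 against 2.13 to 2.22. In KO4, BRIP1 (0.947) was at 1.15 against 1.39 to 1.40, and GCLM (0.889) at 4.61 against 4.00 to 4.07.

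Of the lists, 2 differed between late-stop and early-stop clones, cholesterol synthesis (camera, adjusted p = 0.00138) and replication-dependent histones (adjusted p = 0.000376). Neither passed with an estimated correlation.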

How the results depend on the processing

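The position-centred setting and the setting without distal chromosome 11 were chosen after seeing the data; the cause of the changes below was not tested unless stated. The count of 46 genes for KO against WT became 30 with log2 RPKM above 1 in at least 3 samples (9747 genes tested), 75 with log2(RPKM + 1), 114 with quantile normalization, 169 with weights per group, 28 with at least 1 log2 unit of change, 1 with position centring and 2 without the chromosome 11 stretch. Leaving out single libraries gave 0 to 248. Of the 24 named genes, 24 stayed past the threshold with quantile normalization, 21 with median centring, 15 under the stricter filter, 2 without the chromosome 11 stretch, 1 with position centring, and 0 with the replicate block, without any 1 WT replicate or without KO replicate 4. The late-stop against early-stop count stayed at 0 in the other settings, and leaving out single libraries gave 0 to 276. Without single libraries the counts were 3014 to 5772 in KO1, 1664 to 4823 in KO2, 1620 to 4861 in KO3 and 1099 to 3927 in KO4, and they stayed within 1.5 times the reported count under the other settings. ASH1L kept its direction and did not pass in any setting, with -0.74 to -0.30 when single libraries were left out.

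Of the lists, 0 passed with an estimated correlation in either comparison. With position centring 8 passed for KO against WT and 4 for late-stop against early-stop clones, and without the chromosome 11 stretch 8 passed for KO against WT. Leaving out single libraries gave 1 to 9 lists and 2 to 10 lists.

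Replicate numbers did not pair the samples: deviations of WT and KO libraries with the same number correlated at 0.060, 0.066 and -0.012. With the number as a replicate block 0 genes passed, ASH1L was at -0.74 and 5 lists passed. KO4 has no partner, so the block also takes it out of the contrast; without KO replicate 4 alone 1 gene passed and ASH1L was at -0.74 as well.

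Signs changed for genes that did not pass in the settings given here. PCDHGB4, at -0.01 as reported, was at 0.083 with log2(RPKM + 1), 0.023 with median centring, 0.094 with quantile normalization, 0.047 with position centring, 0.008 without WT replicate 1, 0.545 without KO replicate 3 and -0.395 without KO replicate 4. PCDHGB5, at 0.182 as reported, was at -0.126 with the block and without KO replicate 4, and at 0.531 without KO replicate 3. With position centring MORF4L2 was at 0.131, GLIS3 at -0.061, SC5D at 0.138 and LUM at 0.009. Depth limits low genes most: levels far below 0 stand for few or no reads.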

Other observations

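The lists and stretches below were chosen after the values were seen. The tests of a single step on chromosome 11, of ASH1L loss, of a loss from the ASH1L site, of another cell line and of the list count over splits were written before their results. The adjustment for GC content and length, the fit with 2 steps, the comparison with neighbours, the HNF4A test and the gene count over splits were chosen afterwards. A broad set of transcripts typical of gut and liver epithelium separated the clones. WT cells held AGR2, a secretory pathway gene, at log2 RPKM 8.67, the trefoil factor genes TFF1, TFF2 and TFF3 at 5.88, 5.71 and 4.76, and the fibrinogen genes FGB and FGG at 3.33 and 2.22. In KO1 AGR2 was at -1.79, TFF1 at -0.65, FGB at -4.98 and FGG at -9.70. In KO2 AGR2 was at 9.04 and FGB and FGG were at 5.51 and 4.42, above WT, while TFF1, TFF2 and TFF3 were below it at 5.0, 5.29 and 3.04. KO3 had AGR2 at 9.04 but FGB at 0.45, and KO4 had 5.95 and -3.38.

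Of 70 endodermal and hepatic genes, 38 were tested, on 18 chromosomes. The filter of log2 RPKM above 0 in at least 3 libraries is met by the 3 WT samples alone. A gene above it only in fewer than 3 clones could not enter. The tested genes therefore favour those expressed in WT, and falls are easier to see than rises. Against WT, 37 were lower and 1 higher in KO1, 5 lower and 29 higher in KO2, 29 lower and 2 higher in KO3, and 36 lower and 0 higher in KO4. The medians were -7.81, 1.30, -1.70 and -2.50, and with values under log2 RPKM -2 set to -2, the medians were -3.90, 1.30, -1.72 and -2.45. Chromosome-scale shifts could not account for it, since the KO1 median stayed at -7.57 when genes were set against their neighbours. HNF4A, a transcription factor of liver and gut epithelium and itself 1 of the 38 genes, moved with the list median in 4 of 4 clones. It was at 1.54 in WT and -6.10, 3.41, -0.65 and -0.04 in KO1 to KO4. Without it the list medians were -7.97, 1.27, -1.63 and -2.52. In each clone most list genes were called in the direction of HNF4A, so the test does not single it out. Lower HNF4A stays a candidate explanation. A library of another cell line stays open for KO1: its best single step on chromosome 11 lay 9.79 Mb from the median of the other clones, and its last step of 2 lay among theirs, but steps are measured against WT, so a step of WT alone would appear in any library. The fold changes of KO1 correlated with those of KO4 at 0.754, of KO3 at 0.546 and of KO2 at 0.059. Its levels correlated with those of KO4 at 0.926, of KO3 at 0.881 and of KO2 at 0.788. The values with KO4 speak for a related line, but no unrelated line was analysed here to set a bound. No biological explanation that the design gives was tested, since ASH1L is altered in all 4 clones.

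The lower distal part of chromosome 11 in all 4 clones was not removed by an adjustment for GC content and gene length, after which the highest clone median was -0.60. Loss of DNA copies in the clones is a candidate explanation that the test did not settle, and values against WT do not separate it from a gain in WT. If 1 loss were shared, the best single step along the chromosome would fall at the same place, and a distance over 20 Mb had been set beforehand as evidence against copy loss; the steps lay up to 39.65 Mb apart, which met that bound. The other part of that test was met, with medians of -0.62 to -0.45 in the less expressed and -0.77 to -0.68 in the more expressed genes of the stretch. The bound was ill-chosen, since separate losses need no common end and a fit with 2 steps placed a first step at 46.65 to 47.34 Mb in all 4 clones and the last ones up to 11.38 Mb apart, at 86.62, 88.20, 76.82 and 86.99 Mb in KO1 to KO4. Loss of ASH1L acting on these genes cannot be told apart from this, because 0 clones with intact ASH1L were analysed here.

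The long arm of chromosome 1 in KO1 kept a median of -0.61 after adjustment for GC content and length. A loss from the ASH1L site to the end of the chromosome would leave the genes before the site at their WT level, but the 68 long-arm genes more than 3 Mb before ASH1L had a median of -0.38, which speaks against such a loss as the whole cause. The best single step over the chromosome in KO1 lay at 132.79 Mb, between the arms, and within the long arm at 165.65 Mb, 10.3 Mb from ASH1L. Loss of copies of the whole arm was not tested with DNA.

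By the count over splits chance is not excluded for the genes of KO against WT: 2 of the 35 splits of the 7 libraries, the real one included, gave at least 46 genes. The other set the 3 WT samples and KO2 against the remaining clones, with 105 genes, so it holds part of the real contrast and points to a structure of the samples; the splits that part the WT samples gave 0 genes each. For the gene lists 30 of the 35 splits gave at least the 5 lists of the real one, and the highest other gave 14, so chance cannot be excluded for them.

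CDKN2B, chosen after its value was seen, was at log2 RPKM -9.88 in KO3, the level without reads, while its neighbours CDKN2A and MTAP were at 2.41 and 1.18 there, against WT means of 3.88 and 1.76.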
